A study of Mus musculus with 2 samples.

How the data were processed

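The deposited data are 2 libraries of CD45-selected cells from mouse tumours, 1 from the cepharanthine group (CEP) and 1 from the vehicle group, whose title label reads "Vehide". Groups were taken from the sample titles. Per the labels, tumours were dissociated with collagenase D and DNase I, CD45-positive cells were enriched with antibody and magnetic beads to over 95% purity, and about 30,000 cells per sample were loaded for droplet 3' sequencing with version 3 chemistry. Per the file headers, each matrix holds counts: raw UMIs per gene and cell barcode, with no normalization, over 32285 gene models. No barcode had under 500 UMIs, so the authors' cell calling had already been applied. Set beside the stated number of loaded cells, 9621 CEP and 9989 Vehicle barcodes were deposited. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 5.0.1, while the file headers name version 7.1.0. Whether intronic reads were counted is not given in the sources used here, and the default for this differs between those versions, so levels of genes with long introns depend on it; both libraries carry the same header.

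The study design states 5 biological replicates per group, but nothing in the labels maps cells to animals, so each group was treated as 1 sample and cells were never treated as replicates. No test between conditions, p-value or count of changed genes was computed. The comparisons were the share of each cell class, the share of subsets within a class, the expression of each gene summed over a class, and the median of 27 gene lists, each CEP over Vehicle. These comparisons, the marker genes, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

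Barcodes with at least 200 genes and at most 15% mitochondrial UMIs were kept. Of the CEP and Vehicle barcodes, 77 and 57 had too large a mitochondrial share, including the 42 and 10 with too few genes, leaving 9544 and 9932. Doublets were scored with Scrublet in each library separately. Its automatic threshold marked 3 and 1 cells (0.0314% and 0.0101%), far under the rate that such loading gives, so cells scoring above the limit of the highest 8% were removed instead (716 and 722, with cells tied at the limit kept), a rule chosen after the automatic threshold was seen. The kept cells numbered 8828 and 9210, with median depths of 6200.5 and 5777.5 UMIs. A doublet of cells of 1 class is not found by this score, and a cluster with both T cell and macrophage markers (113 CEP and 97 Vehicle cells, 1.28% and 1.05%) that survived it was left out of all classes.

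Counts were scaled to 10000 per cell and taken as log2 of the value plus 1. The 2000 most variable genes, ranked by dispersion within expression bins in each library and then by mean rank, were used without receptor segment, ribosomal, mitochondrial and haemoglobin genes. Values were scaled, clipped at 10 and reduced to 30 principal components. A graph of the 20 nearest neighbours with shared-neighbour weights was clustered by the Leiden method at resolution 1 with seed 1, both libraries together and with no batch integration, since library and group coincide. Cells of each class with at least 50 cells were clustered again. A cluster took the name of the lineage with most markers detected in at least 25% of its cells at 4 times or more the lower quartile of clusters, with at least 3 markers, and stayed unnamed where its 10 leading genes pointed to another lineage, or where its median depth was under 1/3 of its library's and no leading gene was a marker. The 25% and 4-fold limits, the minimum of 50 cells and the use of a second round were chosen after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.

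Shares carry exact binomial (Clopper-Pearson) 95% intervals and their ratios a log-normal interval. The denominator was all kept cells, and kept leukocytes as an alternative. Main classes had at least 200 kept cells in each library: macrophages, neutrophils and T cells. Conventional dendritic cells and epithelial cells were added after the data were seen although the Vehicle library held under 200 of each. NK and B cells were too few for the lists planned for them. For each class, UMIs were summed per library and given as UMIs per 1000000 UMIs of the class (CPM), with exact Poisson intervals of each sum and an exact conditional binomial interval of the ratio. Sums were 41598269 and 52851087 UMIs in macrophages, 4165906 and 5864819 in neutrophils and 952625 and 1276856 in T cells, so the counting error of a gene at a given CPM is smallest in macrophages and widest in T cells. These intervals leave out the spread between cells, animals and library preparations.

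A list median was the median log2 CPM ratio, with 0.5 UMI added to each sum, over members with at least 50 UMIs in the class, less the median of all genes passing that minimum (11932 genes in macrophages, 6844 in neutrophils, 5363 in T cells). It was ranked among 10000 random lists of the same size drawn from 20 bins of mean expression. A list is said to stand apart where it lies at or beyond the 2.5th or 97.5th percentile; this describes 2 libraries and is no test between conditions, because genes of a pathway move together. Lists with under 5 measured members are given as values only. The 27 lists were the PKC-zeta, NF-kB and PARP1 axis, NF-kB targets, PARP family and DNA repair, type I interferon, interferon-gamma, MHC class I, MHC class II, cytotoxic effector, checkpoint and exhaustion, naive and memory T cell, regulatory T cell, inflammatory macrophage, immunoregulatory macrophage, immunosuppressive myeloid, chemokines, phagocytosis and efferocytosis, dendritic cell maturation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, lysosome, integrated stress and unfolded protein response, apoptosis, cell cycle, dissociation and heat shock, mitochondrially encoded transcripts, and haemoglobin and other-cell transcripts. Some genes belong to several lists, such as Gpnmb, which is in the lysosome and immunoregulatory lists and among the subset markers.

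Named genes were every axis gene with at least 50 UMIs in the cells described; per main class the 5 higher and 5 lower genes whose ratio interval lay farthest from 1 at its nearer bound; and per list and class 2 to 4 members in the direction of most members and the farthest in the other direction. For the leading genes at least 50 CPM in 1 library and at least 100 UMIs were required. Ribosomal, mitochondrial, haemoglobin, receptor segment, Gm and Rik genes were left out. So were genes under 0.2 of their highest main class, which free RNA could explain. Main classes do not include epithelial cells, so free RNA from those was not screened. Epithelial cells held 23263066 of the 78275503 UMIs of kept CEP cells and 3482936 of 71186405 in Vehicle. List members are named mostly for lists that stand apart, and also for the macrophage lysosome list; a few single genes that meet these rules are not reported here, and for single genes named outside this rule (Cd274 in macrophages, leading genes of clusters, and the cell counts behind Il13, Il17a, Prtn3 and Gpnmb) the choice was made after their values were seen. Coordinates are GENCODE vM21 gene spans on mm10.

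Alternatives were doublets kept, the automatic doublet threshold, at most 10% mitochondrial UMIs, at least 500 genes, other Leiden resolutions, each library clustered on its own, classes by marker score per cell, first-round clusters, the leukocyte denominator, the mean over cells of each cell's CPM, cells thinned to 1000 UMIs (8069 and 8516 kept cells reach this depth), class totals without ribosomal and mitochondrial genes, a TMM-style scaling, minimums of 10 and 200 UMIs, 5 UMIs added to each sum, lists without genes within reach of free RNA, and macrophages without 1 cluster made up almost wholly of CEP cells. For neutrophils, 3 lists and 5 genes were also computed with the CEP cells reweighted to the cluster make-up of the Vehicle library, a step added after the data were seen. Shares were recomputed for classes of at least 200 cells and subsets of at least 100. The interval used to compare list medians between settings came from the order of the members' values, which is wider than counting error and so calls fewer medians moved.

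The expression step was tested on simulated counts with known changes. In simulated libraries, 95.1% of macrophage and neutrophil intervals and 95.7% of T cell intervals held the true ratio. Of 200 genes changed by 1.25, 1.5 and 2 fold, the interval left 1 on the right side for 70.1%, 89.6% and 98.5% in macrophages, 46.3%, 80.6% and 97.0% in neutrophils, and 31.3%, 55.2% and 90.9% in T cells. A list of 20 genes raised by 1.25 fold, a true log2 of 0.32, gave medians of 0.31, 0.29 and 0.34. An unchanged list, 1 per class, gave 0.0057, 0.077 and 0.0036, the neutrophil value at percentile 93.5. A neutrophil median of that size can thus arise from counting error alone, and small ones are given little weight. With 1 list per class, how often this happens was not measured. The simulation holds counting error only.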

Results

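Single-cell RNA libraries of CD45-selected mouse tumour cells were compared between a cepharanthine group (CEP) and a vehicle group (Vehicle). Cepharanthine is a bisbenzylisoquinoline alkaloid from Stephania plants. The series title sets the compound against a signalling axis in which protein kinase C zeta (Prkcz) and the transcription factor NF-kB drive PARP1, an enzyme that senses DNA breaks and builds poly(ADP-ribose). The question put to these libraries was which cell classes, pathways and axis genes differed between the groups. The CEP library held 9621 barcodes with 88721774 UMIs and the Vehicle library 9989 barcodes with 81208647 UMIs. Median depth was 6621 and 6236 UMIs, and 2099 and 1991 genes, per barcode. After filters and removal of likely doublets, 8828 CEP and 9210 Vehicle cells were kept. The study design states 5 biological replicates per group, but each group was analysed as 1 library, and no label ties a cell to an animal. No test between conditions was therefore possible, and every interval given is a 95% interval for counting error only. Tumour model, mouse strain, dose and schedule were not given in the sources used here.

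Myeloid cells dominated both libraries, and the CEP library held relatively fewer of the main leukocyte classes and more epithelial cells. Monocyte/macrophage-like cells made up 50.2% (49.1 to 51.2%) of CEP cells and 54.4% (53.3 to 55.4%) of Vehicle cells, and neutrophil-like cells 23.9% and 28.6%, a ratio of 0.834 (0.794 to 0.876). T cell-like cells were 2.55% (2.23 to 2.90%) and 3.57% (3.20 to 3.97%), a ratio of 0.714 (0.604 to 0.843), and conventional dendritic cell-like cells 2.28% and 1.72%, a ratio of 1.33 (1.08 to 1.63). Epithelial-like cells, which carry keratins and should lack the leukocyte protein CD45 used for selection, were 9.52% (8.91 to 10.2%) of the CEP library and 1.42% (1.19 to 1.69%) of the Vehicle library. That is a ratio of 6.69 (5.58 to 8.02) from 840 and 131 cells. Fibroblast/mural-like cells were also a larger share in CEP, at 45 and 17 cells and a ratio of 2.76 (1.58 to 4.82). The suffix is dropped below, and each class name stands for a call from marker genes. For endothelial cells (14 and 11), NK cells (41 and 33), plasmacytoid dendritic cells (17 and 17), mast cells or basophils (22 and 13) and B cells (5 and 13), the interval of the ratio of shares held 1. Cells in clusters that no marker rule named were 9.97% of CEP and 9.16% of Vehicle cells.

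The epithelial cells weigh on every other share because the denominator holds them. Over kept leukocytes alone (7929 and 9051 cells), macrophages were 55.9% and 55.3%, so that the log2 ratio turned from -0.12 to 0.01, and the neutrophil log2 ratio was -0.13 in place of -0.26. T cells kept a lower CEP share over leukocytes (log2 -0.36), but with each library clustered on its own their log2 ratio was 0.16 in place of -0.49. The dendritic cell log2 ratio was 0.41 by clusters and 0.09 when each cell was classed by its marker score. In several classes the fullest cluster was not the same in both libraries. Among neutrophils, the fullest CEP cluster was led by Hcar2 and Ankrd33b (322 cells) and the fullest Vehicle cluster by Steap4, Lrg1 and Hp (516 cells). Dendritic cells gathered most in a Ccl17 and Plet1 cluster in CEP (78 cells) and in an Itgae, Clec9a and Xcr1 cluster in Vehicle (47 cells). For epithelial cells these were an Anln, Cenpf, Cdc20 and Cdk1 cluster in CEP (180 cells) and a Clu, Cldn4 and Id3 cluster in Vehicle (33 cells). Several leads were narrow. The next fullest cluster held 301 CEP neutrophils, 45 Vehicle dendritic cells, 165 CEP epithelial cells and 25 Vehicle epithelial cells. Leads were wider over the next 383 Vehicle neutrophils and 49 CEP dendritic cells.

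**Figure D1:**
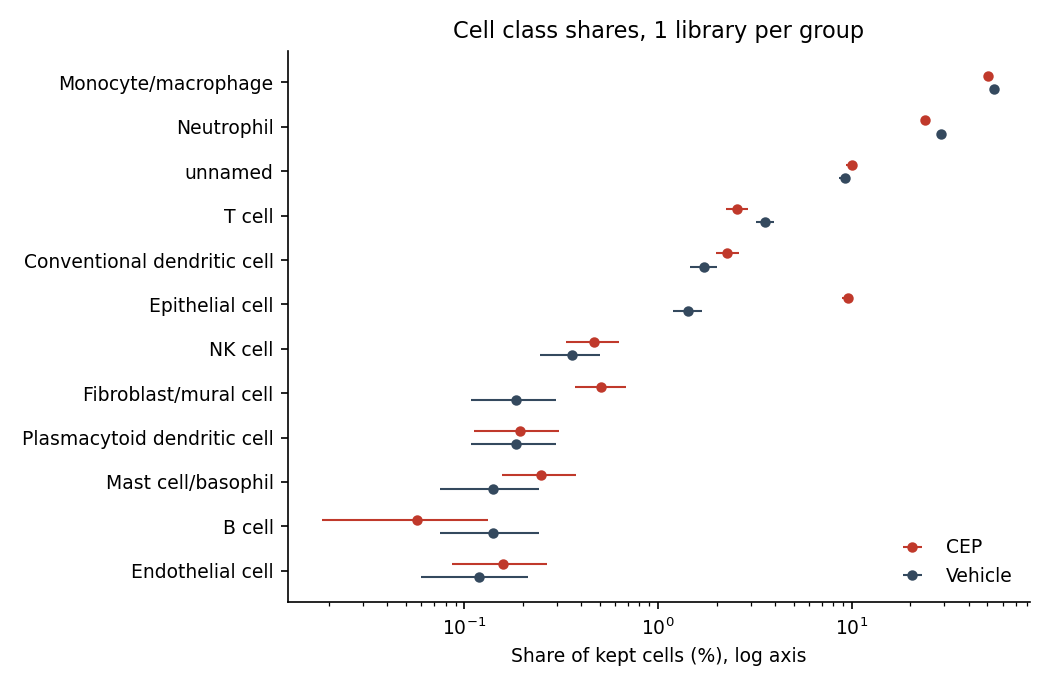
Share of kept cells in each class (percent, log axis) for the CEP and Vehicle libraries, 1 library per group, with exact binomial 95% intervals that cover counting error only. The epithelial class stands apart, at 9.52% in CEP and 1.42% in Vehicle, while macrophages lie close together at 50.2% and 54.4%.

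Within the classes, subset names rest on marker genes that differ in strength, so their shares are given as values and no order is read from them. CD8 T cells were 24.9% of CEP and 22.8% of Vehicle T cells, regulatory T cells 22.7% and 21.3%, and gamma-delta T cells 6.67% and 10.6% (15 and 35 cells). The cluster that took the name of CD4 conventional T cells was 5.33% and 4.86% (12 and 16 cells). It was led by Il13 and Il4, so its share does not stand for all conventional CD4 T cells. The remaining T cell cluster, which expressed Tcf7 and Klf2, was 40.4% in both libraries. Monocytes were 10.6% and 12.4% of the macrophage class, macrophages with complement C1q genes 69.9% and 73.5%, and macrophages with Spp1 and Arg1 19.5% and 14.1%. The last value rested on 1 cluster of 253 CEP and 21 Vehicle cells, without which the shares were 14.6% and 13.7% (log2 0.09 in place of 0.47) and those of C1q macrophages 74.1% and 73.8%. With doublets kept, the log2 ratio of Spp1 and Arg1 macrophages was -0.02. Dendritic cells of the cDC1 kind numbered 74 in each library (36.8% and 46.8%), those of the cDC2 kind 78 and 39 (38.8% and 24.7%), and mature migratory ones 49 and 45 (24.4% and 28.5%). Early neutrophils were 8.82% and 10.0% of neutrophils, neutrophils with tumour-associated genes 76.9% and 70.4%, and a cluster with no subset name 14.3% and 19.6%. The unnamed cluster also scored highest for tumour-associated genes, at 0.278 against 0.284 in a cluster that took the name. It stayed unnamed for too few detected markers, so the tumour-associated share depends on the naming rule.

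Parp1 RNA was slightly higher in CEP macrophages, and in the other classes compared no difference was detectable at this depth. In macrophages Parp1 (ENSMUSG00000026496, chromosome 1, 180568924 to 180601254, plus strand, mm10) stood at 78.9 (76.2 to 81.6) CPM (UMIs per 1000000 UMIs of the class) in CEP and 74.3 (72.0 to 76.7) in Vehicle, a log2 ratio of 0.09 (0.02 to 0.15). In T cells it was 77.7 and 60.3 CPM (log2 0.37, -0.11 to 0.84), and in epithelial cells, a class added after the data were seen although it held only 131 Vehicle cells, 50.9 and 52.0 CPM (log2 -0.03, -0.26 to 0.20). Neutrophils had 6.24 and 4.77 CPM (log2 0.39, -0.44 to 1.21, and 0.99 in cells thinned to 1000 UMIs), a level low enough beside macrophages to be free RNA. Over all kept cells Parp1 was 65.6 and 66.2 CPM (log2 -0.01, -0.07 to 0.04). Prkcz (ENSMUSG00000029053, chromosome 4, 155260129 to 155361361, minus strand) had most of its CEP UMIs in epithelial cells. There it was lower in CEP at 6.19 against 9.76 CPM (log2 -0.67, -1.20 to -0.07, from 144 and 34 UMIs). Its level was higher in T cells than in epithelial cells, at 23.1 CPM in CEP and 25.1 in Vehicle (log2 -0.11, -0.97 to 0.71, from 22 and 32 UMIs). Over all kept cells Prkcz was higher in CEP, the library with more epithelial cells, at 2.47 against 1.22 CPM (log2 1.01, 0.64 to 1.39, from 193 and 87 UMIs).

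Several NF-kB genes of the axis were slightly higher in CEP macrophages. Rela (ENSMUSG00000024927), the p65 subunit, had a log2 ratio of 0.19 (0.10 to 0.28), Nfkb1 (ENSMUSG00000028163), the p105 precursor, 0.14 (0.07 to 0.21), Nfkb2 0.14 (0.04 to 0.23), the kinase gene Ikbkb 0.12 (0.05 to 0.18) and the inhibitor gene Nfkbia 0.10 (0.07 to 0.13). Rel was 0.08 (0.03 to 0.13), but -0.03 when each cell's CPM was averaged. The intervals of Prkci (0.06), Relb (0.02), Chuk (-0.02) and Ikbkg (-0.14) held 0. In T cells Nfkb2 (0.40, 0.00 to 0.79), Nfkb1 (0.34, 0.06 to 0.61) and Rel (0.34, 0.06 to 0.60) lay above 0, and Rela (0.21, and 0.82 in thinned cells), Relb (0.06), Nfkbia (0.07) and Ikbkb (-0.15) did not leave it. In neutrophils Nfkb2 was 0.38 (0.13 to 0.63) and Nfkbia 0.04 (0.00 to 0.09), the latter -0.06 both with averaged CPM and in thinned cells. Prkci (-0.49, and -1.52 in thinned cells), Ikbkb (-0.20), Relb (-0.16), Rel (-0.15), Nfkb1 (-0.05), Ikbkg (-0.03), Rela (0.07) and Chuk (0.17) had neutrophil intervals that held 0. As a list, 9 of 11 measured axis genes lay above the median of all genes in macrophages (list median 0.09, percentile 97.8 of matched random lists), 7 of 9 in T cells (0.22, percentile 98.9) and 5 of 11 in neutrophils (-0.04, percentile 30.1). The macrophage list was at percentile 83.7 in thinned cells and 97.4 with averaged CPM, and the T cell list at 95.5 with averaged CPM and 96.0 with doublets kept.

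Textbook NF-kB target genes, which encode cytokines, chemokines and feedback inhibitors, did not stand apart as a list in macrophages, neutrophils or T cells. They did in the 2 classes added after the data were seen, where they were higher in CEP. Their medians there were 0.13 in conventional dendritic cells (percentile 99.8) and 0.37 in epithelial cells (percentile 100). Above the all-gene median were 15 of 25 in macrophages (median 0.04, percentile 91.4, and -0.05 in thinned cells), 13 of 24 in neutrophils (0.03, percentile 66.3) and 11 of 20 in T cells (0.06, percentile 79.8). Genes of the PARP family and DNA repair had medians of -0.03 in macrophages (6 of 20 above, percentile 24.6) and -0.25 in T cells (2 of 5 above, percentile 6.28). Ratios were taken on summed UMIs per class, so a class counts as 1 sample per group. No axis gene was compared in protein, phosphorylation or activity.

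**Figure D2:**
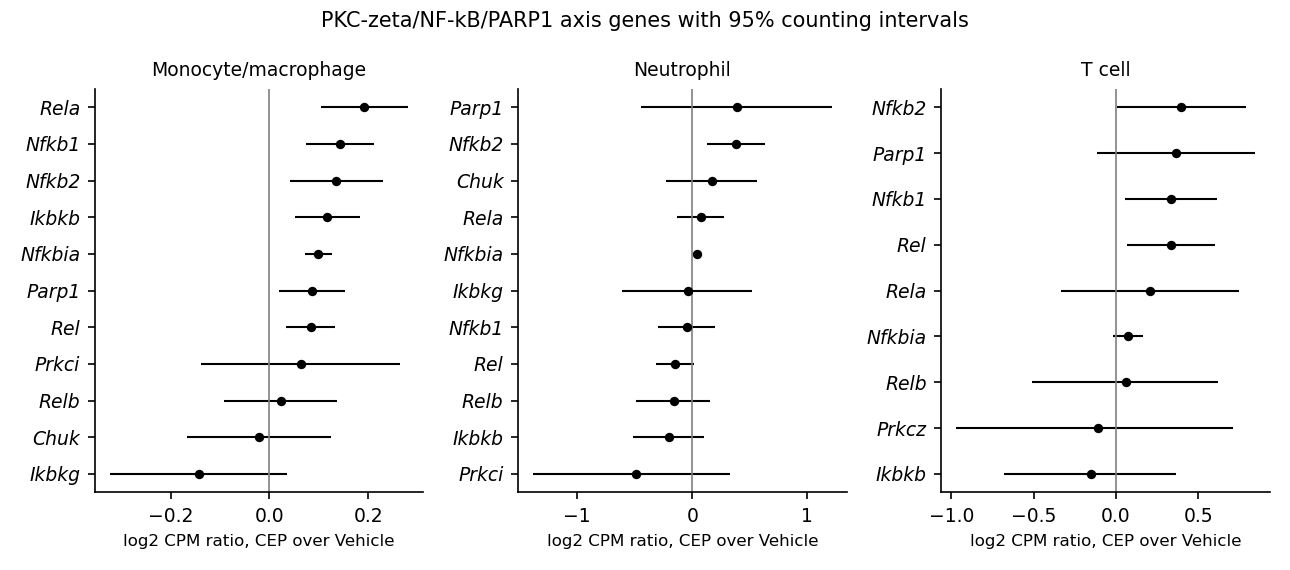
Log2 CPM ratio, CEP over Vehicle, of each measured gene of the PKC-zeta, NF-kB and PARP1 axis in macrophages, neutrophils and T cells, with 95% counting intervals from 1 library per group. In macrophages Parp1 lies at 0.09 and Rela at 0.19, and no macrophage interval lies wholly below 0. Of these classes, only T cells had enough UMIs for Prkcz to be measured.

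Genes induced by interferon-gamma were lower in CEP macrophages and neutrophils, together with genes of antigen presentation. In macrophages 0 of 22 measured list members lay above the all-gene median, and the list median was -0.46, a ratio of 0.729. Gbp2 (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, plus strand), a guanylate-binding protein of cell-autonomous defence, was at 82.8 against 137.0 CPM (log2 -0.73, -0.79 to -0.67). Socs1, a feedback inhibitor of interferon signalling, was at -0.69, the immunity-related GTPase Iigp1 at -0.67 and the nitric oxide synthase Nos2, which was under 0.2 of its neutrophil level, at -0.65. In neutrophils 14 of 17 members lay below, with a median of -0.48 (ratio 0.715), Gbp2 at -0.85, Gbp3 at -0.82, Gbp5 at -0.78 and the transcription factor Irf1 at -0.61, while Irf8 was higher (0.55) at a level that free RNA could reach. Both medians were at percentile 0.0 of matched random lists. A neutrophil cluster led by Rsad2, Slfn4 and Ifit1 held 8.44% of CEP and 14.5% of Vehicle neutrophils (178 and 383 cells), and with the CEP cells reweighted to the Vehicle cluster make-up the interferon-gamma median was -0.34. That cluster is itself set apart by interferon genes, so reweighting removes part of any difference by construction, and the size of the drop does not part cluster make-up from expression. The T cell list had a median of -0.10 (11 of 16 below, percentile 5.05).

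Of the MHC class II genes in macrophages, 12 of 13 lay below the all-gene median, which gave a list median of -0.39 (ratio 0.763, percentile 0.0). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674, plus strand) was at 2749 against 3796 CPM (log2 -0.47), H2-Ab1 at -0.45, the peptide exchange factor H2-DMb1 at -0.45 and H2-Aa at -0.40, while the protease gene Lgmn was at 0.02. MHC class I genes were below the median for 20 of 21 members in macrophages (list median -0.23) and 18 of 21 in neutrophils (-0.29), both at percentile 0.0. Macrophage examples are the peptide transporter Tap1 (-0.39), H2-T23 (-0.37), H2-Q6 (-0.30) and the immunoproteasome subunit Psmb8 (-0.29), with H2-Q7 in the other direction (0.28); H2-Q genes are close paralogs and their counts are uncertain. Neutrophil examples are the class I transactivator Nlrc5 (-0.81), Psmb9 (-0.50), H2-T23 (-0.46) and Tapbp (-0.39), with the chaperone Calr higher (0.30) at a level within reach of free RNA. The neutrophil median was -0.14 with doublets kept and -0.18 (-0.28 to 0.0028) with clusters reweighted. In T cells the class I list had a median of 0.03 (12 of 21 above, percentile 47.0).

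Type I interferon genes were lower in CEP neutrophils, where 19 of 22 lay below the all-gene median (list median -0.28, percentile 0.0), with Ifit2 at -0.89, Usp18 at -0.83, Cmpk2 at -0.77, Rsad2 at -0.61 and Ifi27l2a in the other direction at 0.63. With clusters reweighted, under the limit given above, the median was -0.057 (-0.20 to 0.080) at percentile 5.7 and no longer stood apart. In macrophages the direction depended on the processing: the median was -0.10 on summed UMIs (18 of 26 below, percentile 0.02, with the nucleic acid sensor Zbp1 at -0.33, Oas1a at -0.26 and Isg20 at 0.44), 0.10 both with averaged CPM and in thinned cells, and -0.24 without 1 cluster made up almost wholly of CEP cells. The T cell median was -0.15 (9 of 15 below, percentile 2.71), but 0.12 with doublets kept. Inflammatory macrophage genes had a median of -0.20 (14 of 18 below, percentile 0.0). Nos2, the T cell attracting chemokines Cxcl9 (64.8 against 96.7 CPM, log2 -0.58) and Cxcl10 (-0.54) were lower and Tnf was higher (0.11), but members such as Nos2, Cxcl9, Cxcl10 and Irf1 also belong to the interferon-gamma list. The checkpoint ligand gene Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095, plus strand) was at 103 against 132 CPM in macrophages (log2 -0.36, -0.41 to -0.30).

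RNA quality measures moved along with these lists. Mitochondrially encoded transcripts were higher in CEP neutrophils (13 of 13 above the all-gene median, list median 0.79, with mt-Nd3 at 1.36, mt-Nd2 at 0.95 and mt-Cytb at 0.94), macrophages (11 of 13, 0.19) and T cells (12 of 13, 0.20). With cells held to at most 10% mitochondrial UMIs the neutrophil median was 0.51. Genes induced by tissue digestion and heat were higher in CEP macrophages (18 of 21, median 0.16, percentile 100, with Fosb at 0.41, Egr1 at 0.34, Dnaja1 at 0.30 and Jund at 0.26, and Hspb1 at -0.30). Their medians were 0.10 in neutrophils (13 of 19 above, percentile 96.8) and -0.05 in T cells (13 of 21 below, percentile 5.12). List members are not independent of each other, and 1 library per group cannot part the compound from the animals or the handling.

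The gene that led the macrophage differences was Gpnmb, which encodes a lysosome-associated membrane glycoprotein (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929, plus strand). It stood at 58.5 (56.2 to 60.9) CPM in CEP and 5.58 (4.96 to 6.26) in Vehicle, a log2 ratio of 3.39 (3.22 to 3.57). Part of this came from 1 macrophage cluster of 253 CEP and 21 Vehicle cells, and without it Gpnmb was at 17.1 and 4.46 CPM (log2 1.94, 1.72 to 2.16). The log2 ratio was 4.03 with averaged CPM and 4.21 in thinned cells. A Gpnmb UMI was found in 7.45% of CEP and 1.44% of Vehicle macrophages at median depths of 8804 and 9803.5 UMIs, and in 0.474% and 0.0379% of neutrophils at 1566 and 1670 UMIs. The other leading genes higher in CEP were Syngr1 (log2 0.61), a synaptogyrin, Ltc4s (0.56), the leukotriene C4 synthase, Crem (0.55), a cAMP-responsive repressor, and Fabp5 (0.53), a fatty acid carrier; without that cluster Syngr1 was at 0.44 and Fabp5 at 0.25. Leading lower genes were Gbp2, Sfi1 (-0.70), Socs1, Gbp2b (-0.67) and Iigp1; Gbp2 and Gbp2b are paralogs, so their separate counts are uncertain.

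Immunoregulatory macrophage genes had a median of 0.13 (15 of 21 above, percentile 100), with Gpnmb, Chil3 (1.26), Il10 (0.67, but -0.25 in thinned cells) and Ccl17 (0.63, and 1.53 in thinned cells) higher and the scavenger receptor Cd163 (-0.79) lower. With averaged CPM the list median was 0.06 at percentile 93.1. Chemokine genes were higher as a list (13 of 21, median 0.17, percentile 100, with Cxcl3 at 0.39, Cxcl2 at 0.32, Ccl9 at 0.29 and Ccl3 at 0.25, and the B cell attractant Cxcl13 at -2.65). Cxcl2, Cxcl3 and Ccl3 were under 0.2 of their neutrophil level, within reach of free RNA. Genes of cholesterol synthesis had a median of 0.11 (17 of 22 above, percentile 99.99), with the sterol carrier Stard4 at 0.29, Insig1 at 0.21, Hmgcs1 at 0.21 and Pmvk at 0.14, and Ebp at -0.12. In thinned cells that median was 0.05 at percentile 85.6. Lysosome genes, of interest because cationic amphiphilic compounds gather in lysosomes, had a median of 0.04 (20 of 30 above, percentile 94.1), with Gpnmb, Ctsk (1.59, and 0.54 with doublets kept), Atp6v0d2 (0.51, but -0.08 in thinned cells) and the protease Ctsd (0.46) higher.

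Small shifts in the other direction were seen for hypoxia and glycolysis genes (20 of 25 below, median -0.06, percentile 0.99), with Ankrd37 at -0.21, Ndrg1 at -0.20, Pfkp at -0.20 and Aldoa at -0.12, and Vegfa at 0.15. Cell cycle genes were below the all-gene median for 24 of 30 members (median -0.07, percentile 0.17), with Ccnb2 at -0.32, Tpx2 at -0.31, Bub1 at -0.29 and Mki67 at -0.25, and Tuba1b at 0.05. Oxidative phosphorylation genes had a median of -0.05 (20 of 27 below, percentile 1.96, but 6.58 with doublets kept, 5.66 with averaged CPM, 3.96 at most 10% mitochondrial UMIs and 2.67 without the cluster made up almost wholly of CEP cells), with Atp5b at -0.17, Sdhb at -0.15 and Ndufa1 at 0.25. Lists that did not stand apart in macrophages were immunosuppressive myeloid genes (0.04, 11 of 19 above, percentile 86.1), phagocytosis and efferocytosis (-0.01, 9 of 20, 36.6), dendritic cell maturation (-0.02, 9 of 19, 34.1), integrated stress and unfolded protein response (-0.04, 8 of 22, 8.32) and apoptosis (-0.03, 7 of 19, 18.8). The list of haemoglobin and other-cell transcripts had 5 measured members in macrophages, all of them higher (median 0.54, with Col1a1 at 1.71 and Krt18 at 0.59), but with doublets kept its median was -0.18 and Col1a1 was at -0.63.

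**Figure D3:**
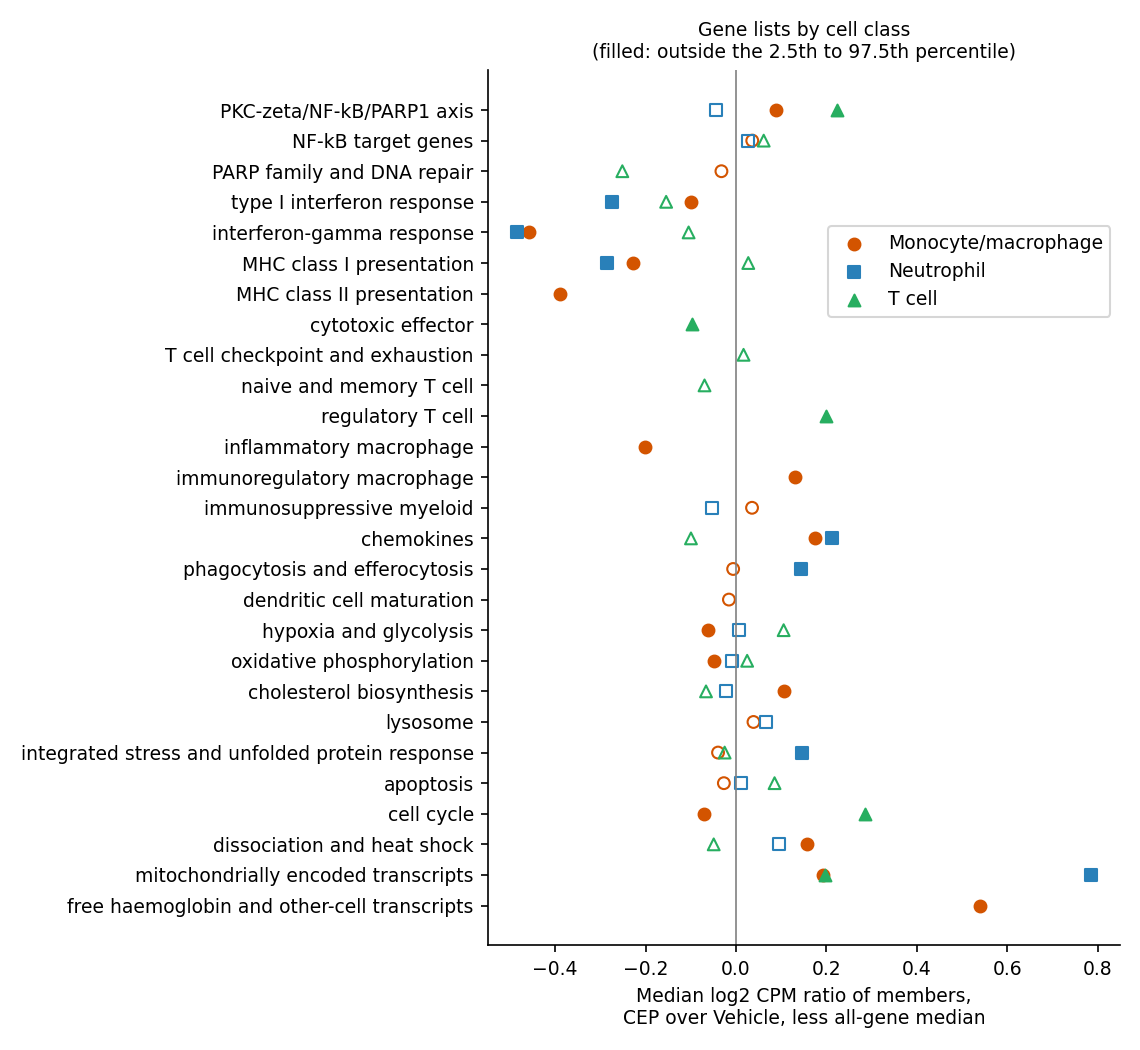
Median log2 CPM ratio of list members, CEP over Vehicle, less the all-gene median, for each gene list in macrophages, neutrophils and T cells, 1 library per group; filled symbols lie outside the central 95% of matched random lists. The interferon-gamma list lies at -0.46 in macrophages and -0.48 in neutrophils, and mitochondrially encoded transcripts at 0.79 in neutrophils.

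CEP neutrophils had more RNA of the chemokine Ccl4 and less of stefin-type and granule protein genes. Ccl4 was at 1469 against 962.5 CPM (log2 0.61, 0.56 to 0.66), and Ifi27l2a (0.63), the carbonic anhydrase Car4 (0.69) and Purb (0.68) were also among the leading higher genes. Lower were Stfa3 (140.2 against 363 CPM, log2 -1.37, -1.51 to -1.24), Cstdc5 (-0.87) and Stfa2 (-0.84), which encode stefin-type protease inhibitors and are close paralogs. Also lower were the granule protein genes Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767, plus strand; 704.3 against 1505 CPM, log2 -1.10, -1.16 to -1.03) and Camp (-0.90), which mark a cluster of 35 CEP and 65 Vehicle cells (1.66% and 2.46% of neutrophils). With clusters reweighted, Ltf was at -0.61 and Camp at -0.44, against -1.27 for Stfa3, -0.81 for Cstdc5 and -0.83 for Stfa2. Neither Ccl4 and the other higher genes nor the chemokine list were reweighted, so a part played by cluster make-up in them was not tested. The granule protease Prtn3 had the highest nearer bound (log2 1.82, 1.59 to 2.07), but 5 cells held 90.3% of its CEP UMIs, and its log2 ratio was -0.32 with averaged CPM. The chemokine list had a median of 0.21 (12 of 18 above, percentile 99.98, with Cxcl3 at 0.33, Cxcl2 at 0.23 and Cxcl10 at -0.44, but 0.02 in thinned cells), and 0.08 at percentile 89.8 in thinned cells.

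Neutrophil genes of the integrated stress and unfolded protein response had a median of 0.15 (14 of 21 above, percentile 99.9), with Manf at 0.52, Hsp90b1 at 0.35, the chaperone Hspa5 at 0.31 and Atf4 at 0.26, but 0.03 at percentile 66.0 without members within reach of free RNA. The phagocytosis list (0.14, 9 of 14 above, percentile 98.7, with Cd93 at 0.76, C1qa at 0.45 and C1qb at 0.36) was likewise at 0.01 without such members and at -0.03 in thinned cells, and at percentile 96.8 with doublets kept and 93.7 with at least 200 UMIs per member. A cluster of 170 CEP and 116 Vehicle cells (8.06% and 4.40% of neutrophils), counted among those with tumour-associated genes, differed from the other neutrophils most by macrophage genes (C1qa, Apoe and Cd74). Other neutrophil medians did not stand apart: immunosuppressive myeloid genes (-0.05, 7 of 17 above, percentile 5.78), hypoxia and glycolysis (0.01, 14 of 25, 37.8), oxidative phosphorylation (-0.01, 12 of 27, 39.9), cholesterol synthesis (-0.02, 7 of 15, 43.5), apoptosis (0.01, 10 of 18, 55.4) and lysosome genes (0.07, 19 of 26, 91.8). Neutrophils carried a median of 1566 and 1670 UMIs, the lowest depth of the main classes.

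In T cells (225 and 329 cells) the leading genes were cytokine and granzyme genes whose UMIs sat in few cells. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand), the cytokine of type 17 and gamma-delta T cells, was at 153 against 1143 CPM (log2 -2.89, -3.15 to -2.65), with a UMI in 8 CEP and 35 Vehicle cells. Other settings put it between -3.53, at most 10% mitochondrial UMIs, and -2.03, in thinned cells. It was lower together with other genes that marked the gamma-delta cluster, Cd163l1 (-1.53) and Serpinb1a (-1.72, and -0.92 in thinned cells). Il13 (log2 2.94) and Il4 (2.62), type 2 cytokines, were higher in CEP, but a UMI was seen in 7 CEP cells for each, and 5 cells held 99.7% of the CEP Il13 UMIs. With averaged CPM the log2 ratios of Il13 and Il4 were 1.51 and 0.68, and in thinned cells 1.17 and 0.86. Among granzymes, Gzmc was higher at 1578 against 599.9 CPM (log2 1.39, 1.27 to 1.52), Gzmf at 1.01 (0.25 with doublets kept) and Gzmd at 1.20 (-0.42 with doublets kept), while Gzmg was lower (-1.49, and -2.38 with doublets kept), as was the enkephalin precursor Penk (-1.54; 5 cells held 92.0% and 92.3% of its UMIs).

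Cell cycle genes were higher in CEP T cells (22 of 28 above the all-gene median, list median 0.29, percentile 100), with Tuba1b at 0.50, Top2a at 0.45 (1.59 in thinned cells), Stmn1 at 0.30 and Tubb5 at 0.29, and Pcna at -0.29. Regulatory T cell genes had a median of 0.20 (12 of 13 above, percentile 99.6, with Ccr8 at 0.59, Tnfrsf4 at 0.22, Il2ra at 0.20, Tnfrsf18 at 0.13 and Areg at -0.47), but 0.02 at percentile 50.6 in thinned cells. Cytotoxic effector genes had a median of -0.10 (14 of 20 below, percentile 0.82, and 3.55 in thinned cells), with Tnf at -1.47 (-0.65 with averaged CPM), Ifng at -1.01 (90 and 243 UMIs in 27 and 41 cells, with 48.9% and 67.5% of them in 5 cells), perforin (Prf1) at -0.68 (0.09 in thinned cells), Ccl4 at -0.52 and Gzmc in the other direction. The remaining T cell lists did not stand apart: checkpoint and exhaustion (0.02, 10 of 17 above, percentile 55.6), naive and memory (-0.07, 5 of 13, 18.9), chemokines (-0.10, 4 of 12, 9.49), hypoxia and glycolysis (0.11, 15 of 21, 96.4), oxidative phosphorylation (0.02, 18 of 27, 53.3), cholesterol synthesis (-0.07, 6 of 16, 23.2), integrated stress and unfolded protein response (-0.03, 8 of 18, 28.9) and apoptosis (0.09, 9 of 15, 85.9). Counting intervals leave out the spread between cells, which is the larger error where few cells carry a gene.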

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

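The tests of depth, of RNA carried between classes and of cluster make-up for the interferon-gamma list, the test of CD45 selection for the epithelial share, and the tests of cluster make-up, depth and free RNA outside the cluster for Gpnmb were chosen only after those results were seen.

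Several gene lists lay beyond matched random lists in one direction in some cell classes and in the other direction in others; these differences between classes were not tested, and the conventional dendritic and epithelial classes were added after the data were seen. List medians, CEP over Vehicle, were as follows. The type I interferon list was at -0.10 in macrophages (0.10 with averaged CPM and in thinned cells), -0.28 in neutrophils (-0.057 with clusters reweighted), 0.60 in conventional dendritic cells and 0.17 in epithelial cells. The interferon-gamma list was at -0.46 in macrophages, -0.48 in neutrophils and 0.29 in epithelial cells. MHC class I genes were at -0.23 in macrophages, -0.29 in neutrophils, -0.17 in conventional dendritic cells and 0.12 in epithelial cells. Inflammatory macrophage genes were at -0.20 in macrophages, 0.16 in conventional dendritic cells and 0.56 in epithelial cells. Hypoxia and glycolysis genes were at -0.062 in macrophages and 0.26 in epithelial cells, and cell cycle genes at 0.29 in T cells, -0.072 in macrophages and 0.25 in epithelial cells.

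The interferon-gamma list was lower in both CEP macrophages and CEP neutrophils. A difference in depth does not account for it, since with every cell thinned to 1000 UMIs the medians were -0.38 and -0.47. In neutrophils the median was -0.53 over the 14 members not marked as within reach of free RNA. The lower neutrophil median thus did not rest on the marked members. Whether macrophage RNA carried into neutrophils played a part cannot be decided from this, because the mark was set on CPM. Neutrophils have far fewer UMIs per cell (CEP medians of 1566 against 8804 in macrophages), so carried RNA weighs more in their CPM. A shift of cells between macrophage clusters is argued against as the whole cause by the median within clusters, -0.33 (range -0.51 to -0.03, lower in CEP in 12 of 12 clusters compared), although the cluster made up almost wholly of CEP cells was not among those compared and had a median of 0.80 over 10 members. Of those compared, 1 had 4 measured members, under the minimum of 5. The macrophage cluster led by Cxcl9, Cxcl10 and Ifit2 held 229 CEP and 464 Vehicle cells, and its own median was -0.03. A part played by macrophage cluster make-up therefore stays open, and list genes help to define these clusters too. A shift between neutrophil clusters is argued against as the whole cause, since with the CEP neutrophils reweighted to the Vehicle cluster make-up the median was still -0.34 (-0.44 to -0.095) in place of -0.48, although list genes help to define these clusters and reweighting removes part of any difference by construction. Beside a part played by cluster make-up and by carried RNA, an effect of the compound on interferon supply or response stays open. So does a difference between animals or library preparations. With 1 library per group these cannot be told apart. RNA quality also differed, with mitochondrially encoded transcripts higher in CEP neutrophils (median 0.79) and macrophages (0.19), and its part was not tested.

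The epithelial share in the CEP library was 6.69 times that in the Vehicle library despite CD45 selection. Weaker selection that let every non-leukocyte through alike stays open: the ratio of epithelial cells to fibroblasts and endothelial cells (59 CEP and 28 Vehicle cells) was 3.04 times as high in CEP (1.80 to 5.05, counting error only), but a difference in tumour make-up between animals would also give this with 1 library per group. Leukocyte genes in CEP epithelial cells with doublets kept had a median level of 0.524% of that in macrophages (0.293 to 0.766% over 8 genes). The cells classed as epithelial thus showed little sign of leukocytes still attached. This cannot decide whether attached leukocytes pulled epithelial cells through the selection. Joined cells could have parted before loading, or have fallen outside a class named by epithelial markers. A selection that lost leukocytes and left the most abundant tumour cell type, more viable tumour cells in the CEP suspension, and a chance difference between 2 preparations all stay open and were not tested. No reading of tumour size or cell death follows from this share.

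Gpnmb was higher in CEP macrophages. Free RNA is argued against by CEP neutrophils, which held 9.43% of the macrophage CPM, and 6.56% (4.16 to 9.85%) of the UMIs per cell of macrophages outside the cluster made up almost wholly of CEP cells, although 32.3% of their CPM, since neutrophils have far fewer UMIs per cell. Depth is argued against because CEP macrophages had the lower depth, a median of 8804 against 9803.5 UMIs. That difference would lower their share of cells with a Gpnmb UMI. In macrophages thinned to 1000 UMIs that share in CEP was 9.50 times that in Vehicle (6.12 to 14.8). The thinned value keeps the cluster made up almost wholly of CEP cells and adds no separate test of depth. That cluster carried part of the Gpnmb difference, since without it the log2 ratio was 1.94 in place of 3.39. Of the 12 other clusters compared, Gpnmb was higher in CEP in 11, with an interval above 1 in 9. In 1 cluster it was lower in CEP (45 and 87 UMIs, log2 -0.57, interval below 1). A response of macrophages to the compound and a difference between the animals or preparations behind each library both stay open as hypotheses.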

How the results depend on the processing

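No replicate was left out and no split of samples made with 1 library per group. No paired analysis was possible because the groups share only replicate number 1 and the results come from no test. Depth limits T cells and neutrophils most. Settings without the cluster made up almost wholly of CEP cells, with the automatic doublet threshold and with first-round clusters were chosen after seeing the data. Values are log2, with the reported value in brackets; the cause was not tested in any case unless named. Of 54 values for 5 class shares, 44 stayed within the interval, 8 moved and 2 turned direction (counted as turned only where the reported interval left 0 or the list stood apart, otherwise as moved); of 32 for 10 subset shares 24, 6 and 2; of 592 for 58 lists 568, 19 and 5; of 1948 for 305 single genes 1631, 294 and 23. TMM-style scaling, minimums of 10 and 200 UMIs and 5 UMIs added moved no list beyond its interval, but with 200 UMIs neutrophil phagocytosis genes were at percentile 93.7. Under 5 members were left, and no value is given here, for the axis, PARP, naive and cholesterol lists in T cells (thinned cells, 200 UMIs) and the other-cell list in macrophages (thinned cells, 200 UMIs, no free RNA).

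Class shares: with each library clustered on its own, T cells 0.16 [-0.49], macrophages -0.028 [-0.12], epithelial cells 2.24 [2.74]; in thinned cells, macrophages -0.071, neutrophils -0.35 [-0.26]; over leukocytes, a denominator without epithelial cells, macrophages 0.014, neutrophils -0.13; by marker score, conventional dendritic cells 0.094 [0.41], epithelial cells 2.44. With at least 500 genes per cell, neutrophils were at -0.37. Subset shares: by marker score, T cells with naive genes 0.35 [0.00], C1q macrophages -0.025 [-0.07], Spp1/Arg1 macrophages 0.16 [0.47], tumour-associated neutrophils 0.068 [0.13]. Spp1/Arg1 macrophages were at 0.072 at second-round resolution 0.5 and at -0.017 with doublets kept. Without the cluster made up almost wholly of CEP cells, they were at 0.088 and C1q macrophages at 0.0057.

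Lists in thinned cells: NF-kB targets in macrophages -0.050 [0.04], type I interferon in macrophages 0.10 [-0.10], phagocytosis in neutrophils -0.028 [0.14], oxidative phosphorylation in neutrophils -0.057 [-0.01]. In thinned T cells: checkpoint -0.080 [0.02], regulatory 0.019 [0.20], hypoxia -0.027 [0.11], oxidative phosphorylation 0.13 [0.02], stress response -0.20 [-0.03]. Lists with averaged CPM: type I interferon in macrophages 0.10 and, in T cells, PARP and DNA repair -0.50 [-0.25], MHC class I -0.057 [0.03], checkpoint -0.082, cell cycle 0.37 [0.29]. Lists with doublets kept: in T cells, type I interferon 0.12 [-0.15], stress response 0.13; in neutrophils, MHC class I -0.14 [-0.29], hypoxia -0.076 [0.01], oxidative phosphorylation 0.081, dissociation 0.16 [0.10]. The other-cell list in macrophages was at -0.18 [0.54] with doublets kept and -0.10 at most 10% mitochondrial UMIs, where the neutrophil mitochondrial list was at 0.51 [0.79]. Without the cluster made up almost wholly of CEP cells, type I interferon in macrophages was at -0.24.

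Single genes whose reported interval left 0 and that turned, averaged CPM: in macrophages Rel -0.033 [0.08], Cxcl1 -0.020 [0.19], Gas6 -0.13 [0.24], Marcksl1 -0.015 [0.15]; in neutrophils Nfkbia -0.056 [0.04], Prtn3 -0.32 [1.82], Bax -0.0077 [0.20]. In thinned cells: macrophage Cxcl1 -0.056, Mre11a 0.18 [-0.23], Il10 -0.25 [0.67], Atp6v0d2 -0.084 [0.51], Tuba1b -0.041 [0.05]; neutrophil Nfkbia -0.060, Cxcl10 0.021 [-0.44]; T cell Calr -0.17 [0.26], Psme1 0.094 [-0.19], Prf1 0.091 [-0.68], Ccr7 -0.44 [0.54], Hspa8 -0.0035 [0.22]. With doublets kept: T cell Gzmd -0.42 [1.20], macrophage Col1a1 -0.63 [1.71]. At most 10% mitochondrial UMIs: Gzmd -0.33, Col1a1 -0.48.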

Other observations

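The classes described here, the lysosome test and the genes given for single clusters were chosen after the data were seen, and their values carry the same limit of 1 library per group. The reach of free RNA was not computed for the dendritic and epithelial classes, nor was free RNA from them screened in the other classes.

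Conventional dendritic cells (201 CEP and 158 Vehicle cells) had higher type I interferon RNA in CEP. Above the all-gene median were 20 of 21 list members (list median 0.60), with Isg15, a ubiquitin-like modifier, at 461 against 221 CPM (log2 1.06, 0.89 to 1.24), Ifi27l2a at 1.02, Ifi44 at 1.41 and Ifit2 at 2.04, and Ifi205 at -0.28. The interferon-gamma list did not go along (median -0.0017, 9 of 18 above), nor did MHC class II genes (0.05, 7 of 13 above), and MHC class I genes were lower (-0.17, 17 of 21 below, with the immunoproteasome genes Psmb9 at -0.37 and Psmb8 at -0.36). NF-kB target genes had a median of 0.13 (14 of 24 above), with the feedback inhibitors Nfkbiz at 0.72, Tnfaip3 at 0.70 and Nfkbia at 0.47 higher and Tnf at -1.87. Chemokine genes were at 0.26 (11 of 17 above, with Ccl17 at 0.60) and dendritic cell maturation genes at 0.08 (13 of 19). Beside these, dissociation genes had a median of 0.11 (13 of 21 above) and mitochondrially encoded transcripts 0.21 (10 of 13), and the axis list stood at 0.17 (8 of 9, with Nfkbia and, at 0.29, Rel above 0, and intervals that held 0 for Rela at 0.25, Chuk at 0.21, Parp1 at 0.16, Relb at 0.15, Nfkb1 at 0.096, Ikbkb at 0.096 and Nfkb2 at -0.066). The leading genes were the neutrophil transcripts S100a8 (2.01) and S100a9 (1.85), with Fam110a (1.39) and on the lower side Cyp26b1 (-1.53), Apoe (-1.06), Cxcl1 (-1.07) and Lyz2 (-0.95). Cluster make-up differed between the libraries within this class, with cDC2-like cells at 38.8% in CEP and 24.7% in Vehicle.

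Epithelial cells (840 CEP and 131 Vehicle cells, median 26429 and 26213 UMIs) had more RNA of chemokine, interferon, hypoxia and cell cycle genes in CEP. Cxcl10 was at log2 1.95 (1.65 to 2.29) and the monocyte attractant Ccl2 at 129 against 46.8 CPM (1.46, 1.24 to 1.70), and the chemokine list had a median of 0.67 (14 of 18 above). The interferon-gamma list was at 0.29 (20 of 24 above, with Cxcl9 at 1.19 and Gbp2 at 0.59), the reverse of macrophages and neutrophils, the MHC class I list at 0.12 (18 of 21) and the MHC class II list at -0.14 (3 of 11). NF-kB targets were at 0.37 (19 of 23 above, with Tnfaip3 at 0.49 and Nfkbiz at 0.46), next to the axis genes Relb (0.53), Nfkb1 (0.52), Nfkbia (0.45), Rela (0.37), Prkci (0.37) and Nfkb2 (0.28). The intervals of Rel (0.26), Chuk (0.12), Ikbkg (-0.077) and Ikbkb (-0.27) held 0, and 8 of 12 axis genes lay above the all-gene median. Hypoxia and glycolysis genes were at 0.26 (23 of 25 above, with Ero1l at 0.89, Ndrg1 at 0.87, Bnip3 at 0.86 and the glucose transporter Slc2a1 at 0.70, and Ddit4 at -0.32). Stress response genes were at 0.16 (20 of 22 above, with Atf3 at 0.45 and Chac1 at 2.04) and cell cycle genes at 0.25 (24 of 30, with Top2a at 0.60, Rrm1 at 0.54 and Ube2c at -0.32). Cluster make-up differed as well: a cluster led by Adm and Csf3, with Car9 and Ndrg1, held 125 CEP and 5 Vehicle cells, and a cycling cluster led by Anln and Cenpf held 180 and 18. Dissociation genes were higher too (0.16, 17 of 21), while mitochondrially encoded transcripts were at 0.04 (9 of 13). Other leading genes were Mt2 (1.30) and Hist1h1b (1.28), and on the lower side Wfdc18 (-3.83), Msmp (-1.97), Ly6c1 (-1.27), Ccn2 (-1.05) and Tslp (-0.98).

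Over all kept cells together, where class shares and expression mix, axis genes other than Parp1 and Prkcz were at 0.70 (Prkci), 0.41 (Nfkbia), 0.33 (Nfkb2), 0.29 (Rela), 0.22 (Nfkb1), 0.13 (Relb), -0.05 (Chuk), -0.13 (Ikbkg), -0.20 (Ikbkb) and -0.27 (Rel).

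A macrophage cluster of 253 CEP and 21 Vehicle cells, with a median of 3419.5 UMIs, held much of the Gpnmb RNA. Beside Gpnmb (1643 CPM in the cluster, 9.95 in other macrophages) it was rich in the monocyte surface gene Ly6c2 (676 and 18.6 CPM), Ly6a (1300.0 and 18.3), the lipid carrier and droplet genes Fabp5 (5479 and 532) and Plin2 (2071 and 346), the protease Ctsl (5972 and 796) and Isg15 (1929 and 725). It was low in the antigen presentation genes Cd74 (2156 and 15870.0) and H2-Aa (938 and 5733) and in C1qa (1595 and 5473). Because Gpnmb is a lysosomal gene and cepharanthine a cationic amphiphilic compound, lysosomal genes might have been higher across CEP macrophages. Without that cluster, the lysosome list of 30 members had a median of 0.01 at percentile 69.4 of matched random lists, against 0.039 at percentile 94.1 with it, and Ctsd stayed at 0.38, so a broader difference in lysosomal RNA stays open.

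Among cells without a class name, a cluster led by Dcstamp, Cdh1 and Ccl24 held 200 CEP and 221 Vehicle cells (2.27% and 2.40%). A small cluster led by Ctsk, Acp5 and Mmp9, genes typical of osteoclasts, held 32 and 38 cells (0.363% and 0.413%) at a median of 14614 UMIs. A cluster led by Trf, Vegfa and Hcar2 held 38 and 33 cells (0.430% and 0.358%), and a mixed cluster with Cbr2, Cd163 and T cell genes 18 and 30 (0.204% and 0.326%). Low-depth clusters held 146 and 122, 113 and 77, 87 and 90, 99 and 69, and 34 and 67 cells.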
